A study of Mus musculus with 192 samples.

How the data were processed

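Kidney RNA was sequenced from 192 mice of a cross between a line carrying a Col4a5 mutation, a model of X-linked Alport syndrome, and Diversity Outbred males, which descend from several inbred founder strains and so differ in genotype from mouse to mouse. Per the labels' protocols, frozen kidney was powdered, RNA was extracted with a Qiagen kit and libraries were made with an Illumina TruSeq RNA kit. The labels gave the sex and the Diversity Outbred generation of each mouse, which made 6 groups: 12 female and 14 male mice of G14, 55 and 52 of G16, and 30 and 29 of G19. The design text states that siblings of both sexes were taken from each sire, but the labels do not name the pairs, so no pair term was fitted. Mice that share a sire are related, and the tests treated them as independent.

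The authors deposited TPM, a transcript abundance scaled for length to a fixed total, per the labels' description and the values, for 46517 Ensembl mouse genes. The aligner, the counter, the genome build and the annotation version are not given in the sources used here. The TPM of each mouse summed to 1000000, and 9891 genes were at 0 in every mouse, so no filter on low genes had been applied. TPM keeps no sequencing depth: the depth of each library is unknown, and no counting interval was computed. Because the total is fixed, a rise in abundant transcripts lowers the TPM of all others. No count test was used. The highest correlation between 2 mice over genes was 0.98, and no libraries held identical values. Gene symbols and positions came from an annotation of GRCm38, which may not be the build of the authors; 46005 IDs had a symbol and 512 had none.

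Values were tested as log2(TPM + 1), so a fold change understates the change of low genes. The 15161 genes with a mean of at least 1 TPM over all mice were tested with limma 3.58.1 in R 4.3.3 (limma-trend, two-sided moderated test) with terms for sex and generation fitted to all 192 mice, so that the 6 groups shared an estimate of the spread. The Benjamini-Hochberg threshold was 0.05, and this limma adjusted p is meant wherever an adjusted p is given for a gene. An F test of the sex by generation terms asked whether the sex difference varied over the 3 generations.

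There were 41 gene lists, written before the data were examined, as were the design, the scores and the rule for named genes. They covered type IV collagen and basement membrane, podocyte, proximal tubule, thick ascending limb, distal convoluted tubule, principal and intercalated cells, endothelium, mesangial and smooth muscle cells, fibrosis, tubular injury, macrophages, T cells, B and plasma cells, neutrophils, complement, interferon response, MHC class II, cell cycle, fatty acid oxidation, oxidative phosphorylation, cholesterol synthesis, male-biased and female-biased kidney genes, the renin-angiotensin system, phosphate and vitamin D, unfolded protein and integrated stress, immediate early genes, NRF2 targets, Y-linked genes, X inactivation and escape, ribosomal proteins, mitochondrially encoded genes, nuclear retained RNA, blood, adrenal, adipocyte, urothelium, skeletal muscle, liver and exocrine pancreas. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether the genes of a list move one way on balance. A list needed at least 3 tested members; adrenal had 2, skeletal muscle 1 and exocrine pancreas 1, which left 38 lists.

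A score was the mean over a list's tested members of the z score of log2(TPM + 1) across the 192 mice. Scores were correlated within each sex by Pearson's r and Spearman's rho with two-sided permutation tests of 100000 resamples, whose smallest p is 1e-05; the 10 relations formed a family for adjustment, as did the 14 of single genes. For the ratio of standard deviations (SD) between the sexes, each sex's generation means were removed first and sex labels were permuted within generation. For a difference of r between the sexes, scores were centred within sex and generation and scaled within sex before labels were permuted. Where a gene belonged to the injury score, it was left out of the score it was compared with. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Annotated transcripts of 4 genes were compared with those of Cwc22 by blastn 2.17.0, which found all 13 Cwc22 transcripts when they were searched against themselves.

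Named genes were Col4a5, Col4a3 and Col4a4, the 10 largest differences in each direction between the sexes among genes past the threshold with the same direction in all 3 generations (Y-linked genes and Xist aside), up to 4 members with the smallest adjusted p in each list described, the 5 largest differences in each direction per generation contrast with the same direction in both sexes, the 5 smallest p of the interaction, and Havcr1, Lcn2, Col1a1, Fmn1 and the score members with the highest and lowest r. Predicted genes were named only where fewer than 5 others qualified. Genes outside this rule are said to have been chosen after their values were seen. One gene that the rule names among the list members is not reported here.

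The fit was tested on simulated data with 50 genes changed per size among 15161. For sex it recovered 86% of genes changed by 0.25 on the log2 scale and 98% at 0.5; for G19 against G14 the shares were 58% and 84%, and for the interaction 34% and 74%. Among 14561 unchanged genes it made 21, 11 and 7 false calls. The simulated genes and mice varied independently, whereas real genes move together and siblings are related. These shares and false calls may therefore not hold for the real data. In 100 simulated sets the correlation test called 5 sets with a true r of 0 and 87 with a true r of 0.3, and the SD ratio test called 3 sets with a true ratio of 1 and 96 with a ratio of 1.5.

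Alternatives were pseudocounts of 0.1 and 0.5, filters at a mean TPM of 0.1 and 5 and no filter, rescaling each mouse by the median ratio to the geometric mean, quantile normalization, robust empirical Bayes, array weights, the injury score as a covariate, 3 residual principal components as covariates, single generations and single sexes. Leaving out 4 mice whose sex transcripts contradicted the label, leaving out 1 mouse of G19 for Cwc22 and Il1f9, and testing lists after quantile normalization or with scaling and an estimated correlation together were added after the data had been seen.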

Results

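Kidney transcriptomes of 192 mice carrying the Col4a5 mutation were compared by labelled sex and by Diversity Outbred generation. Col4a5 encodes an X-linked chain of the type IV collagen of the glomerular basement membrane. Males carry only the mutant X-linked copy and females are mosaic for it, so every comparison of the sexes is also one of mutation dose. No group without the mutation was labelled, so sex and dose cannot be told apart here. The cross also lets genetically distinct mice with the mutation be compared. Values were TPM as deposited by the authors, with 95 mice labelled male and 97 labelled female, and between 22551 and 25896 genes above 0 per mouse. The sequencing depth is unknown.

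Col4a5 (ENSMUSG00000031274, X chromosome, 141475385 to 141689234 on GRCm38) averaged 10.6 ± 2.36 TPM (SD, n = 95) in labelled males and 16.8 ± 2.65 TPM (n = 97) in labelled females. The difference was -0.63 on the log2(TPM + 1) scale (SE 0.0372, adjusted p = 4.54e-38, limma), and it was -0.67, -0.67 and -0.53 in G14, G16 and G19. Col4a3, a partner chain on chromosome 1, was 78.8 ± 12.98 TPM in males and 88.4 ± 12.3 TPM in females (log2 -0.17, SE 0.0308, adjusted p = 3.5e-07). Col4a4, the other partner, was 54.99 ± 7.98 against 54.2 ± 6.91 TPM and did not pass the threshold (log2 0.02, adjusted p = 0.581). After scaling by the median ratio, which moved the median difference of all tested genes from 0.13 to 0.02, it was -0.10 (adjusted p = 0.00125).

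**Figure D1:**
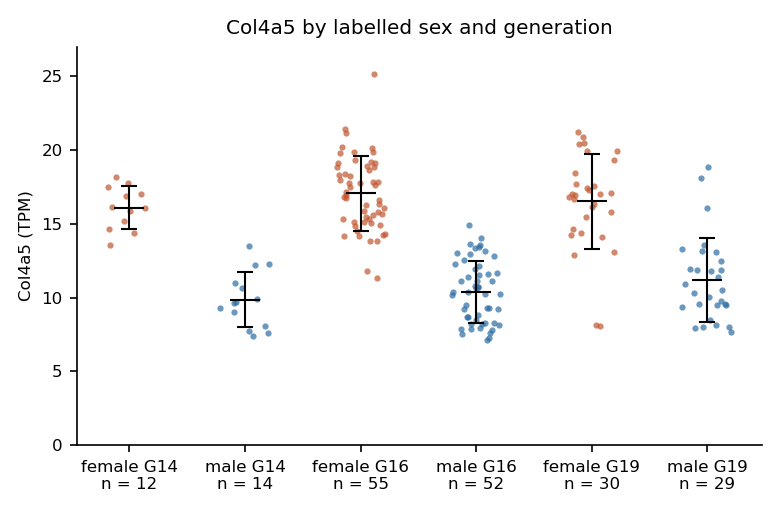
Col4a5 in TPM (vertical axis, from 0) for each mouse of the 6 groups of labelled sex and generation, with the group mean and SD as black bars. Labelled males averaged 10.6 TPM and labelled females 16.8 TPM.

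Sex transcripts contradicted the label in 4 mice. Xist, the RNA that silences an X chromosome, was 345 TPM in the mouse labelled male G16 replicate 16 and 339 TPM in male G19 replicate 14, where the median of labelled males was 0.343 TPM. The summed TPM of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty was 0.434 and 0.447 in these 2 mice. Conversely, Xist was 1.21 and 0.494 TPM in the mice labelled female G19 replicates 22 and 29, against a median of 255 TPM in labelled females. These 2 mice had 1169 and 833 TPM of Acsm3 and 657 and 918 TPM of Slc7a13, both male-biased. Col4a5 was 13.4 and 18.1 TPM in the 2 mice labelled male. These values lay inside the range of the other labelled males and also inside that of the other labelled females (11.3 to 25.1 TPM). It was 8.10 and 8.16 TPM in the 2 labelled female, under the 11.3 TPM of the lowest of the other labelled females. All 1570 Y-linked genes were listed at 0 in all 97 mice labelled female. All mice were kept under their labels, and sexes below are those of the labels.

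The kidneys of the 2 sexes differed in 11718 of 15161 genes (77.3%, limma). Of these, 9013 were higher in males and 2705 higher in females, and 365 and 163 differed at least 2-fold (769 and 241 with a pseudocount of 0.1). The share of calls higher in males was 76.9% with TPM as deposited, 54.5% after scaling by the median ratio and 47.4% after quantile normalization. The median difference over all tested genes was 0.13, 0.02 and -0.01 on the log2 scale in these settings. In all 3 generations 96.6% of the differing genes had the same direction. With the tubular injury score as a covariate 2242 genes were higher in males and 9040 in females, and the median over all tested genes was -0.11.

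Slco1a1, an organic anion transporter, had the largest male-higher difference, at 188 ± 141 TPM in males and 7.63 ± 49.4 TPM in females (63.1-fold, log2 5.98, SE 0.226, adjusted p = 2.48e-63). Its female mean rested on the mice labelled female G19 replicates 22 and 29, and without the 4 mice that contradicted the label it was 0.812 ± 0.832 TPM (n = 95) against 192.1 ± 139.6 TPM (n = 93, log2 6.25). The medium-chain acyl-CoA synthetase Acsm3 was 60.4-fold higher, the cytochrome P450 Cyp2j13 57.0-fold, the amino acid transporter Slc7a13 53.2-fold, the glucuronosyltransferase Ugt2b37 34.3-fold and Cyp4a12a 19.1-fold. Cyp7b1 (11.1-fold), Timd2 (11.04-fold), Pzp (10.8-fold) and Cyp4b1 (8.81-fold) followed. The largest female-higher difference was in the glucuronosyltransferase Ugt1a2, at 38.9 ± 201.1 TPM in males and 1245 ± 324 TPM in females (log2 -6.97, SE 0.19, adjusted p = 2.63e-85). The amino acid transporter Slc7a12 was 24.1-fold higher in females, Slc22a29 17.6-fold, the prolactin receptor Prlr 13.6-fold, Cyp4a14 11.2-fold and Slc17a2 10.6-fold. Akr1c18 (9.88-fold), Ceacam2 (9.51-fold), Igf2 (9.19-fold) and the betaine methyltransferase Bhmt (7.74-fold) completed the 10. Without these 4 mice, left out as a choice made after the data had been seen, Ugt1a2 was 9.69 ± 11.2 TPM in males and 1271 ± 272 TPM in females (log2 -7.28), so the mice labelled male G16 replicate 16 and G19 replicate 14 raised its male mean.

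Markers of tubule segments were lower in males. Of 18 proximal tubule genes 15 were lower and 2 higher (median log2 -0.55, camera adjusted p = 2.85e-10; adjusted p = 0.183 with an estimated correlation). The gluconeogenic enzyme Pck1 was 742 ± 267 TPM in males and 1882 ± 538 TPM in females (log2 -1.38), Gatm of creatine synthesis differed by -1.13, and the endocytic receptors Cubn and Lrp2 by -0.96 and -1.07. In the thick ascending limb 7 of 8 genes were lower (median -0.45; adjusted p = 0.00684 with an estimated correlation), among them the channel Kcnj1 (-0.60), the cotransporter Slc12a1 (-0.51), Ppp1r1a (-0.79) and Egf, at 290.0 ± 193 against 858 ± 212 TPM (-1.94). In the distal convoluted tubule 5 of 6 were lower (median -0.94; adjusted p = 0.00422 with an estimated correlation), with Klhl3 at -0.86, Slc12a3 at -1.03, Calb1 at -1.13 and Pvalb at -2.23. All 7 intercalated cell genes were lower (median -0.47; adjusted p = 0.00684 with an estimated correlation), including Slc4a1 (-0.97), Atp6v1g3 (-0.47), Slc4a9 (-0.57) and Slc26a4 (-0.80).

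Glomerular and endothelial markers were lower by smaller amounts. Of 13 podocyte genes 7 were lower and 0 higher (median -0.13, camera adjusted p = 0.00167; adjusted p = 0.358 with an estimated correlation), and 11 were lower after scaling by the median ratio (median -0.24) and 12 after quantile normalization (-0.29). They included Podxl (-0.34), the slit diaphragm gene Nphs1 at 17.4 ± 6.48 against 25.7 ± 7.11 TPM (-0.56), Magi2 (-0.32) and Clic3 (-0.46). Of 11 endothelial genes 7 were lower (median -0.11, camera adjusted p = 0.00014; adjusted p = 0.262 with an estimated correlation), with Ehd3 at -0.48, Kdr at -0.39, Tek at -0.25 and Flt1 at -0.19; all 11 were lower after either scaling (median -0.23 and -0.26). Of 12 genes of type IV collagen and basement membrane 7 were higher and 2 lower, or 6 and 5 after either scaling, and camera did not call the list (adjusted p = 0.749). Col4a2 was 0.72 higher in males, Agrn 0.61 and Col4a1 0.66, while Col4a5 was lower. With the injury score as a covariate these 3 genes were at -0.10, -0.11 and -0.24, where the median of all tested genes was -0.11, and camera called the list lower (adjusted p = 0.0461; adjusted p = 0.742 with an estimated correlation).

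**Figure D2:**
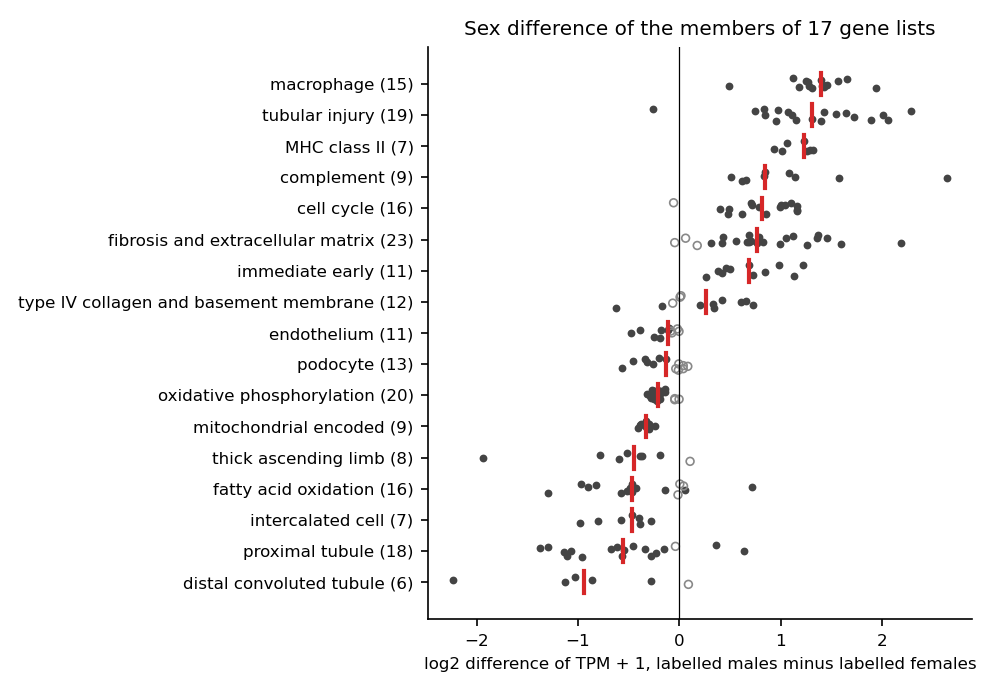
Male minus female difference on the log2(TPM + 1) scale (horizontal axis) for each tested member of 17 gene lists (vertical axis, number of members in brackets). Filled points passed an adjusted p of 0.05 in limma, open points did not, and red bars are list medians, from 1.40 in macrophage genes to -0.94 in distal convoluted tubule genes.

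Injury, matrix and immune genes were higher in males. Of 19 tubular injury genes 18 were higher and 1 lower (median 1.31, camera adjusted p = 9.07e-05; adjusted p = 0.46 with an estimated correlation), with the cytokine Il34 at 71.6 ± 35.2 against 17.3 ± 11.8 TPM (log2 2.01), Sox9 at 1.31, the chemokine Ccl2 at 1.89 and Dcdc2a at 1.54. Of 23 fibrosis genes 20 were higher (median 0.77, camera adjusted p = 0.00609; adjusted p = 0.666 with an estimated correlation), led by Timp1 (2.18), Tnc (1.37), the crosslinking enzyme Lox (1.26) and Col3a1 (1.59). All 15 macrophage genes were higher (median 1.40, camera adjusted p = 0.000113; adjusted p = 0.46 with an estimated correlation). Lyz2 was 553 ± 480 against 144 ± 208 TPM (1.94), Tyrobp differed by 1.46, Itgam by 1.41 and Fcer1g by 1.29. All 9 complement genes (median 0.85) and all 7 MHC class II genes (median 1.23) were higher (camera adjusted p = 0.00656 and 0.00726; adjusted p = 0.46 for both with an estimated correlation). They included C4b at 44.8 ± 33.1 against 6.22 ± 7.75 TPM (2.65), Cfb (0.66), Cp (1.09), Serping1 (0.85), Ciita (1.01), H2-Aa (1.29), Cd74 (1.32) and H2-Ab1 (1.23). With the injury score as a covariate Cp and Serping1 were at -0.13 and -0.10, close to the median of all tested genes of -0.11. Of 16 cell cycle genes 15 were higher (median 0.82, camera adjusted p = 0.00106; adjusted p = 0.542 with an estimated correlation), among them Ccnb1 (1.17), Ccnb2 (1.04), Birc5 (1.10) and Cdc20 (1.002). All 11 immediate early genes were higher (median 0.69, camera adjusted p = 0.0139; adjusted p = 0.559 with an estimated correlation), with Atf3 at 1.22, Egr2 at 1.13, Junb at 0.73 and Fos at 0.85.

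Genes of mitochondrial metabolism were mostly lower in males. Of 16 fatty acid oxidation genes 11 were lower and 2 higher (median -0.47, camera adjusted p = 8.54e-08; adjusted p = 0.104 with an estimated correlation). Hadha (-0.49), Acaa2 (-0.90) and Hadhb (-0.51), of the mitochondrial pathway, were lower. Of 20 oxidative phosphorylation genes 17 were lower (median -0.21, camera adjusted p = 7.54e-13; adjusted p = 0.0829 with an estimated correlation), with Atp5o at -0.25, Cox4i1 at -0.25, Cox6c at -0.25 and Atp5a1 at -0.26. All 9 mitochondrially encoded genes were lower (median -0.32, camera adjusted p = 1.96e-06; adjusted p = 0.183 with an estimated correlation), but after quantile normalization 8 were, with a median of -0.14 and no camera call (adjusted p = 0.194). Mitochondrial genes took 14.6% of TPM in males and 18.1% in females. Of 6 blood genes 4 were lower and 1 higher (median -1.11, camera adjusted p = 0.00643; adjusted p = 0.212 with an estimated correlation), with Alas2 at -1.02, Hbb-bt at -1.32, Hbb-bs at -1.21 and Hba-a2 at -1.19; camera did not call this list after quantile normalization (adjusted p = 0.084).

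Of 10 genes listed as male-biased in kidney 9 were higher in males (median 3.305; adjusted p = 0.0345 with an estimated correlation), including Cyp2e1 at 2.73, and of 8 listed as female-biased 7 were lower (median -3.20; adjusted p = 0.000138 with an estimated correlation), including Abcc3 at -2.91. Of the 38 lists camera called 9 higher and 13 lower in males, of which 7 were called with an estimated correlation. The male-biased, female-biased, Y-linked and X inactivation lists are among these 7. They were planned as checks of the sex labels, so their calls are not findings about the kidney. Fry called 35 lists. With an estimated correlation 3 lists were called after scaling by the median ratio, those of female-biased, Y-linked and X inactivation genes. All 3 are label checks, so no other list was called in that setting. The calls of the thick ascending limb (adjusted p = 0.112), distal convoluted tubule, intercalated cell and male-biased lists (adjusted p = 0.0826 for each) were lost there. Counts adjusted over the list alone equalled those over all genes tested in 35 lists. Median, mean and camera direction differed in sign in 4 lists. After scaling by the median ratio the list medians were -0.68 for proximal tubule, -0.57 for thick ascending limb, 1.22 for tubular injury, 1.28 for macrophage, 0.65 for fibrosis and -0.34 for oxidative phosphorylation. With the injury score as a covariate, where the median of all tested genes was -0.11, the fibrosis median was -0.19 (1 member higher and 15 lower) and camera did not tell the list from other genes (adjusted p = 0.904). The medians were 0.07 for macrophage (5 higher and 1 lower, camera adjusted p = 0.0269), -0.14 for proximal tubule (6 and 10, 0.474), -0.55 for thick ascending limb (0 and 7, 0.0154) and -0.07 for oxidative phosphorylation (2 and 14, 0.697). The macrophage and thick ascending limb calls were lost with adjusted p = 0.742 and 0.461 with an estimated correlation. The tubular injury list was not read here, because its own score was the covariate. In this setting 12 of the 22 camera calls were lost: podocyte, proximal tubule, principal cell, fibrosis, complement, MHC class II, cell cycle, fatty acid oxidation, oxidative phosphorylation, immediate early, mitochondrially encoded and blood (adjusted p from 0.0589 to 0.913).

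Counts of genes that differed between generations changed with the setting. Between G14 and G16 11 genes differed (7 higher and 4 lower in G16), between G16 and G19 6 (4 and 2), and between G14 and G19 297 (253 and 44). The unadjusted p was under 0.05 for 3047, 778 and 4647 genes, and 2, 0 and 9 of the called genes differed at least 2-fold. Array weights gave 3622 genes between G14 and G16, and between G14 and G19 there were 549 after scaling by the median ratio, 613 with the injury score as a covariate and 488 without the 4 mice that contradicted the label. The splicing factor gene Cwc22 was 272 ± 218 TPM in G14 (n = 26), 108 ± 195 TPM in G16 (n = 107) and 32.1 ± 134 TPM in G19 (n = 59), a difference of -2.78 from G14 to G19 (SE 0.427, adjusted p = 9.24e-06). The G19 mean rested on the mouse labelled male G19 replicate 16, at 1046 TPM; the median of G19 was 13.6 TPM. Without this mouse, a choice made after the data had been seen, the G19 mean was 14.6 ± 3.90 TPM (n = 58) and the difference -2.89. The cytokine gene Il1f9, also on chromosome 2, was 9.07 ± 7.06, 4.10 ± 6.26 and 1.66 ± 4.30 TPM (log2 -1.62, adjusted p = 3.9e-05), and in G19 1.11 ± 0.481 TPM without the same mouse, which had 33.9 TPM (log2 -1.69). Coagulation factor F5 was lower in G19 than in G14 by -0.96, Slc22a30 by -0.99 and Rhox6 by -0.51. Ighv14-3 (0.94), the T cell gene Cd8a (0.83), Ighv5-9 (0.79), Klra2 (0.78) and the vitamin D hydroxylase Cyp24a1 (0.72, 62.6 ± 21.02 against 41.2 ± 23.97 TPM) were higher.

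**Figure D3:**
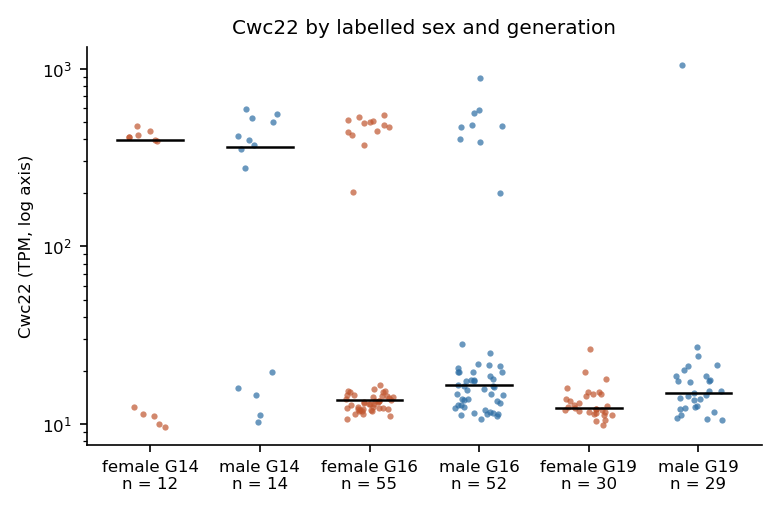
Cwc22 in TPM (vertical log axis) for each mouse of the 6 groups of labelled sex and generation, with the group median as a black line. Mice lay either under 30 TPM or above 100 TPM, and 16 of 26 mice of G14, 22 of 107 of G16 and 1 of 59 of G19 lay above.

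In G16 against G14, Klra2 (0.64), C920006O11Rik (0.28), Gm20743 (0.28), E230016M11Rik (0.24) and Fam204a (0.23) were higher, and Cwc22 (-1.87), Il1f9 (-1.08), F5 (-0.85) and the potassium channel Kcnk5 (-0.34) were lower. In G19 against G16, Gm16316 (0.51), Gm27316 (0.42), ENSMUSG00000090108 (0.24) and the insulin-degrading enzyme Ide (0.20) were higher, and Plekhb1 (-0.32) and Cgrrf1 (-0.08) were lower. Of 20 oxidative phosphorylation genes 5 were lower in G19 than in G14, and 19 adjusted over the list alone (median -0.11; adjusted p = 0.00686 with an estimated correlation). Of 8 T cell genes 3 were higher (8 adjusted over the list alone, median 0.51), as were 3 of 16 interferon genes (14, median 0.41); their camera calls (adjusted p = 0.000123 for both) were lost with adjusted p = 0.343 and 0.403 with an estimated correlation. Camera called 15, 13 and 20 lists in G16 against G14, G19 against G16 and G19 against G14, of which 2, 0 and 1 were called with an estimated correlation and 0 in all after scaling by the median ratio; fry called 0, 0 and 7. Males alone and females alone gave 0 genes for every contrast, and generation may stand for a batch, which the labels do not separate.

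The sex difference was not shown to vary over generations: 0 genes passed the limma F test, with 251 at an unadjusted p under 0.05. The 5 smallest p values were those of Slc7a10, whose male minus female difference was -0.88, -0.19 and 0.28 in G14, G16 and G19, and of Ctbs, Bcl6, Adamts8 and Hc (adjusted p = 1.0 for each).

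Across mice of a sex, kidneys with a high tubular injury score had high fibrosis and macrophage scores and low proximal tubule scores. For fibrosis r was 0.971 in 95 males and 0.948 in 97 females (rho 0.970 and 0.917), and for macrophage genes 0.975 and 0.953 (rho 0.973 and 0.911). For the proximal tubule r was -0.808 and -0.810 (rho -0.926 and -0.644), and for fatty acid oxidation -0.594 and -0.628 (rho -0.628 and -0.437). Each of these 8 r had p = 1e-05, the smallest that the permutations can give (adjusted p = 1.11e-05). The rank correlations had that p too, except for fatty acid oxidation in females (p = 2e-05). Without the 2 mice farthest from the median injury score r was 0.969 and 0.925, 0.973 and 0.934, -0.820 and -0.734, and -0.610 and -0.429 in the same order. Within G14, G16 and G19 r ranged from 0.913 to 0.980 for fibrosis, 0.917 to 0.987 for macrophages and -0.886 to -0.698 for the proximal tubule. For fatty acid oxidation it was -0.455 and -0.419 in G14 (adjusted p = 0.13 and 0.194).

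TPM of most genes rose with the injury score, which sets the background for these values. In males, 10000 random lists of 15 genes had a median r of 0.929 with the injury score (95% of lists from 0.817 to 0.961), and in females 0.764 (0.484 to 0.879). The macrophage r of 0.975 and 0.953 lay above all of them. The fibrosis r lay above 99.8% of random lists of 23 genes in males and above all in females. After scaling by the median ratio random lists of 15 genes had a median r of 0.221 in males (95% of lists from -0.783 to 0.846) and 0.156 in females (-0.525 to 0.696). Macrophage r was then 0.959 and 0.937, fibrosis 0.952 and 0.925, proximal tubule -0.863 and -0.865, and fatty acid oxidation -0.844 and -0.845. Random lists of the sizes of the last 2 reached -0.911 and -0.9035 in males, beyond these r. In females the lowest were -0.792 and -0.791.

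The podocyte score rose with the injury score in males (r = 0.648, rho 0.690, adjusted p = 1.11e-05) and missed the threshold by r in females (r = 0.175, p = 0.085; rho 0.239, adjusted p = 0.018). Its r was below the random lists' median of 0.925 and 0.751, and after scaling by the median ratio it was 0.00394 in males (adjusted p = 0.969) and -0.289 in females (adjusted p = 0.00448). Among single genes, the injury marker Lcn2 had r = 0.949 in males and 0.939 in females, Havcr1 0.846 and 0.562, Col1a1 0.955 and 0.916, and Anxa2, the member with the highest r, 0.989 and 0.959. The lowest were Slc27a2 in males (-0.884) and Slc13a3 in females (-0.769). For the podocyte gene Fmn1 r was 0.807 and 0.439, and -0.126 and -0.111 after scaling by the median ratio (adjusted p = 0.24 and 0.281). All these single-gene r before scaling had p = 1e-05, the smallest possible.

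**Figure D4:**
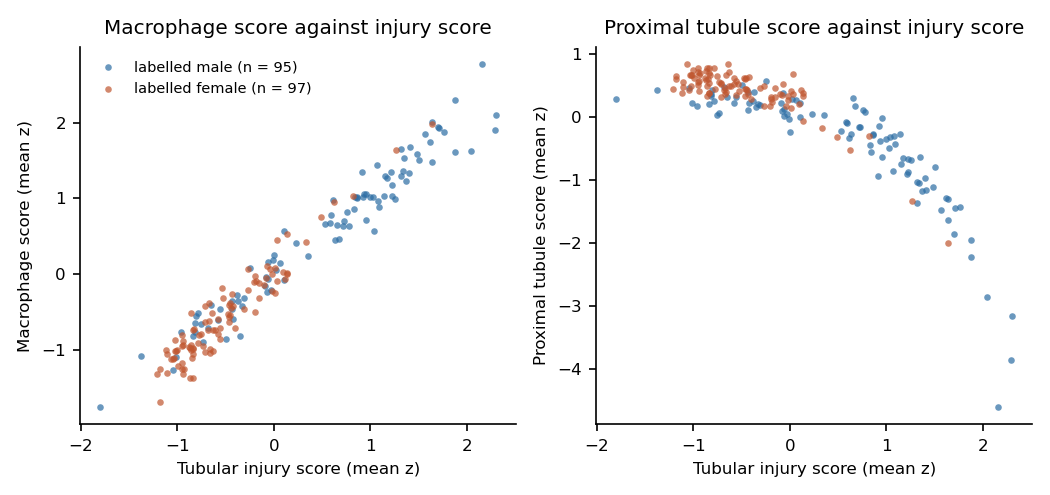
Macrophage score (left) and proximal tubule score (right) against the tubular injury score, all as mean z scores, with a point per mouse (95 labelled male in blue, 97 labelled female in orange). The macrophage score rose with injury in both sexes (r = 0.975 and 0.953) and the proximal tubule score fell (r = -0.808 and -0.810).

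Males differed more from each other than females did. The SD of the injury score, after removing generation means, was 0.931 in males and 0.513 in females, a ratio of 1.82 (p = 1e-05, the smallest possible, adjusted p = 2e-05). For the fibrosis score the SDs were 1.02 and 0.570, a ratio of 1.78 (p = 2e-05, adjusted p = 2e-05). In G19 alone the ratios were 1.46 and 1.501 and missed the threshold (adjusted p = 0.0682 for both).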

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

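The tests of explanations in this part were chosen, or their criteria reworded, after the result they measure had been seen, as was leaving out 4 mice; for the random lists, the shared transcripts of Cwc22 and both tests of proximal tubule loss, the criterion was replaced or narrowed after a first outcome.

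The r of scores with tubular injury differed between the sexes in 4 cases. The injury score was more spread in males (SD ratio 1.82), and a wider spread can by itself raise the size of r. Scaling within sex does not remove this, so a difference of r need not be a different relation. The r of the podocyte score was 0.485 higher in males (0.646 against 0.161 after removing generation means, adjusted p = 0.00015, permutation of sex labels), but 0.299 higher with adjusted p = 0.281 after scaling by the median ratio. The r of the macrophage score was 0.0238 higher in males (0.977 against 0.954), and its adjusted p of 0.0486 lay on the threshold: it was 0.0538 without the 4 mice that contradicted the label and 0.281 after scaling. For the male-biased kidney genes the difference was -0.771 (r = -0.669 in males and 0.101 in females, adjusted p = 2e-05), -0.705 after scaling and -1.08 without the 4 mice (-0.832 and 0.249). For the female-biased kidney genes it was 0.604 (0.249 and -0.355, adjusted p = 0.00012). After scaling it was 0.410 (adjusted p = 0.00167) and the male r turned sign (-0.105 and -0.515). Without the 4 mice it was 1.02 (0.472 and -0.545, adjusted p = 1e-05, the smallest possible).

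The macrophage score rose with the injury score, and so did almost any list of genes. Random lists of 15 genes had a median r of 0.929 in males, within 0.1 of the macrophage r of 0.975, which lay above all 10000 lists. The criterion as first written was met on both sides by these values and so did not separate the explanations; the one used here asks for the position among random lists and was set afterwards. By it, most random sets of genes did not correlate as strongly. In males the margin was small, since the highest list of 15 genes had r = 0.974. Random lists of 13 genes reached 0.977 in males, so some sets of genes did correlate as strongly. The random genes were not matched for how closely macrophage genes move together. A shift shared by all genes is argued against as the source of the whole r, since after scaling by the median ratio random lists had a median r of 0.221 in males and 0.156 in females while the macrophage r was 0.959 and 0.937, again above all lists.

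The male-biased score fell with the injury score in males (r = -0.669, rho -0.806, p = 1e-05 for both, the smallest possible). Without the 2 mice labelled male with female transcripts r was -0.830, so these mice do not account for it. Whether it goes beyond the loss of proximal tubule transcripts cannot be told apart: the partial r given the proximal tubule score was -0.210 (p = 0.0422, adjusted p = 0.0843) with TPM as deposited and -0.0147 (adjusted p = 0.882) after scaling. Without these 2 mice it was -0.420 (adjusted p = 8e-05) and -0.238 (adjusted p = 0.0439). On the unadjusted p of the first value alone this explanation had been set aside; the criterion was then changed to ask for the adjusted p under both scalings.

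In 4 mice Xist, Y-linked and sex-biased transcripts contradicted the label. A mixed library is argued against, since at most 0.474% of the median of the labelled sex's marker was left, and a swap within G16 has no partner, with 0 mice labelled female carrying male transcripts there. A wrong sex label remains open for all: 4 of 4 lay inside the other sex's range of the male-biased minus female-biased score (-1.82, -1.64, 2.28 and 2.07, against 0.0246 to 2.64 in the other males and -1.97 to -0.746 in the other females). A swap within G19 may account for 1 mouse labelled male, since 2 mice labelled female carried male transcripts there; no biological explanation was tested. Y genes may have been left out when the values of mice labelled female were made: the 2 mice labelled male with female transcripts had 15 to 25 Y genes above 0, whereas all 97 labelled female, including 2 with male transcripts, had 0.

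Most genes that differed by sex were higher in labelled males. A loss of proximal tubule transcripts alone is argued against, because after scaling by the median ratio 19 of 21 markers of the thick ascending limb, distal convoluted tubule and intercalated cells were lower in males. By the criterion used first, a camera call for these lists with an estimated correlation, this explanation had passed, since adjusted p was 0.112, 0.0826 and 0.0826. That criterion was replaced because calls of single members bear more directly on whether these markers rose. Such calls count markers that move together as independent. A larger share of TPM in abundant transcripts of females stays open: the 10 most abundant genes took 30.4% in females and 27.01% in males, and scaling lowered the share of calls higher in males to 54.5%. More injury in males, a difference that goes with sex and with the dose of the mutation, may also contribute. With the injury score as a covariate 21.5% of the male-higher genes stayed higher, though this score follows the same shift of the whole table.

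Cwc22 and Il1f9 fell from G14 to G19. A library batch that went with generation is argued against, since 10 mice of G14 lay under 30 TPM of Cwc22 and 16 above 100, with 0 of 192 mice between. Reads shared with annotated Cwc22 transcripts are argued against as the source of the genes that moved with it, since 0 of 4 (Il1f9, Gm42764, Gm42900, Gm11261) matched one over 100 bases at 90% identity; introns and extra copies of the locus were not searched, and the explanation was narrowed to transcripts for that reason. A strain variant at Cwc22 may account for the separate levels. Of the 20 genes that moved most closely with Cwc22, 10 lay on chromosome 2, against 7.89% of the genes tested (one-sided Fisher's exact p = 7.98e-07). This test counts genes linked on a chromosome as independent. Il1f9 (r within groups 0.983) is on chromosome 2 but starts at 24186476. The other chromosome 2 genes among the 20 start at 76406508 or beyond, and their r was at most 0.683 (Tfpi). Gm42764 and Gm42900 are on chromosome 5 (0.962 and 0.940) and Gm11261 is on chromosome 4 (0.860). Linkage to Cwc22 does not account for the genes on chromosomes 4 and 5. Whether it accounts for Il1f9, which is far from the other chromosome 2 genes and had a higher r, was not tested. Founder genotypes were not analysed here.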

How the results depend on the processing

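Leaving out the 4 mice that contradicted the label, or male G19 replicate 16 for Cwc22 and Il1f9, and testing lists after quantile normalization or with scaling and an estimated correlation together, were chosen after the data had been seen; the other alternatives were planned, and the tests of other splits were read after the results. No paired analysis was possible because the labels do not name the sibling pairs, and replicate numbers only number the mice within a group. Of 104 alternative values of main results with a test, 95 kept their direction and their side of the threshold, and of 136 counts 91 were within 1.5 times the count reported; except where stated, the cause was not tested. Depth is unknown in TPM, so its limit on low genes could not be given.

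Counts of sex differences changed with scaling and injury. A pseudocount of 0.1 gave 769 genes at least 2-fold higher in males, since it compresses low genes less. Scaling by the median ratio gave 5055 female-higher genes, and quantile normalization 5342 male-higher and 5929 female-higher. With the injury score as a covariate 2242 were male-higher, 9040 female-higher and 147 at least 2-fold male-higher, and 13 lists were called, among them the injury list, for which the test is void because its score was the covariate. With fewer mice, G14 alone gave 3332 and 1545, and G19 alone 5764 and 1632. Of the 9013 male-higher genes, 8878 remained so without the 4 mice.

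Counts between generations were unstable. For G16 against G14 they were 17 at a mean TPM of 0.1, 5 at a mean TPM of 5 and 17 with no filter. They were 23 with the median ratio, 29 with quantile normalization, 3622 with array weights, 32 with the injury score and 7126 with 3 residual components. For G19 against G16 they were 3 at a mean TPM of 5, 72 with array weights, 49 with the injury score and 1199 with residual components. For G19 against G14 they were 79 at a mean TPM of 5, 111 with no filter, 549 with the median ratio, 137 with array weights, 613 with the injury score, 8338 with residual components and 488 without the 4 mice. Residual components are unrelated to the design by construction and only shrink the error. Males alone gave 0, 0 and 0 genes and females alone 0, 0 and 0, with fewer mice. With an estimated correlation 7 lists differed by sex and 3 by generation. Together with the median ratio 3 and 0 did, the 3 being checks of the sex labels. With quantile normalization 4 and 0 did. Fry called 35 and 7.

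Among scores, podocyte r fell to 0.00394 in males and reversed to -0.289 in females after scaling by the median ratio. It was -0.00209 in females in G19 alone (adjusted p = 0.992). It passed the threshold in females in G16 alone (0.321) and without the 2 farthest mice (0.211). Fatty acid oxidation r missed it in G14 alone (-0.455 in males, -0.419 in females). The SD ratios missed it in G19 alone (1.46 for injury, 1.501 for fibrosis). Fmn1 r was lost after scaling, at -0.126 and -0.111 (adjusted p = 0.24 and 0.281). In females it also missed the threshold in G14 alone (0.408, permutation adjusted p = 0.191) and in G16 alone (0.263, 0.0519). Slc27a2 r missed it in females in G14 alone (-0.507, permutation adjusted p = 0.102). Changes of sign in sex differences of named genes came with a shift of all tested genes, whose median was 0.13 as deposited, 0.02 with the median ratio, -0.01 with quantile normalization and -0.11 with the injury score as a covariate. Col4a4 was -0.10 with the median ratio, -0.10 with quantile normalization and -0.068 with the injury score. With that score Col4a2 (-0.10), Agrn (-0.11), Cp (-0.13) and Serping1 (-0.10) lay close to that median and Col4a1 (-0.24) below it. Of 1463 alternative values of named genes by sex 1446 were the same, 9 weaker and 8 reversed, and of 338 by generation 255 were the same and 83 weaker. Most of these genes were picked from the same data for large differences or small adjusted p, so the counts are not an independent check.

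In 100 splits of the mice, real one included, 1 gave as many genes as the 11718 by sex (highest other 4976), so chance can be excluded there by the share under 0.05. Only 1 gave as many as the 11 between G16 and G14 (highest other 1), a share under 0.05 as well. For the 6 between G19 and G16, 2 splits did, also under that share, but the other of these called 5761, so this share rests on few splits and few genes. Splits between generations part siblings, which share a generation, so they exclude chance only if siblings vary independently. Siblings are related, so chance is not taken as excluded for these 2 contrasts of generation. For the 297 between G19 and G14, 5 did (highest other 8787), so chance cannot be excluded. For the interaction the real count was 0, so every split had to give at least as many (highest other 5122). The splits therefore cannot bear on chance there. Some splits of generation called many more genes than the real groups did. What these splits had in common was not tested.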

Other observations

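The tests on X-linked genes in this part, and those of lists after quantile normalization or with scaling and an estimated correlation together, were chosen after the result had been seen; the other tests of gene lists were planned.

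Immune cell lists beyond macrophages had higher members in males, without a camera call in TPM as deposited. All 6 B and plasma cell genes (median log2 0.98, camera adjusted p = 0.178), 7 of 8 T cell genes (0.59, 0.17) and all 3 neutrophil genes (0.72, 0.216) were higher. Camera called T cell genes after scaling by the median ratio (adjusted p = 0.0374) and quantile normalization (0.026), and B and plasma cell genes after the latter (0.0427; 0.0534 with the median ratio), but neither with an estimated correlation (adjusted p from 0.428 to 0.498). Of 16 interferon genes 10 were higher and 3 lower (camera adjusted p = 0.754). All 6 urothelium genes (0.575; 3 of them after quantile normalization), 15 of 18 ribosomal protein genes (0.216) and 4 of 7 liver genes, with 2 lower (0.579), were higher, with camera adjusted p in brackets; the ribosomal list was called after both scalings (0.0374 and 0.0262; adjusted p = 0.518 and 0.536 with an estimated correlation), and the liver list with the injury score as a covariate (0.0308; adjusted p = 0.461 with an estimated correlation). Of 17 cholesterol synthesis genes 11 were higher and 2 lower (0.666), or 9 and 6 after the median ratio and 7 and 6 after quantile normalization; camera called them with that covariate (0.0154; adjusted p = 0.461 with an estimated correlation). Of 7 NRF2 targets 6 were higher and 1 lower (0.216), of 10 stress genes 7 and 1 (0.575; 5 and 3 after the median ratio), and of 8 mesangial and smooth muscle genes 4 and 2 (0.819).

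Of 7 principal cell genes 4 were lower in males, 6 adjusted over the list alone and 7 after either scaling (camera adjusted p = 0.00626; adjusted p = 0.358 with an estimated correlation). Of 7 renin-angiotensin genes 4 were lower and 1 higher (camera adjusted p = 0.0724), of 7 phosphate and vitamin D genes 3 and 3 (0.17), of 5 adipocyte genes 1 and 0 (0.229), and of 3 nuclear retained RNAs 0 and 1 (0.756). Of 6 genes of X inactivation and escape 5 were lower in males (adjusted p = 0.0276 with an estimated correlation). All 4 tested Y-linked genes were higher (adjusted p = 0.00103 with an estimated correlation), but they were listed at 0 in all 97 mice labelled female, including 2 with male transcripts, so this compares them with a listed 0.

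Some X-linked genes near Col4a5, chosen after their values were seen, were lower in males. Among X-linked genes with a mean of at least 0.3 TPM, and with 0.1 added to the mean TPM of each sex, 5 of 29 within 3 Mb of Col4a5 were at least 2-fold higher in females, against 11 of 544 elsewhere on the X chromosome (two-sided Fisher's exact p = 0.000691). Xist, which lies elsewhere on the X chromosome and was higher in females, was not counted among the 11. On the log2(TPM + 1) scale of the tested genes, Nup62cl (-2.12) and D330045A20Rik (-1.06) were the 2 of 25 that reached 2-fold, against 3 of 443 elsewhere (p = 0.0248). The 5 were D330045A20Rik, Nup62cl (0.827 ± 1.03 against 6.96 ± 2.82 TPM), Frmpd3, Col4a6 (0.203 ± 0.162 against 0.920 ± 0.403 TPM) and Chrdl1 (5.47 ± 2.37 against 11.6 ± 3.86 TPM). A haplotype carried along with the mutation may account for the 5, but their number depends on the scale; the window and the threshold were chosen after the cluster was noticed, and no genotype was tested.

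Males varied more than females in most genes. The sires were Diversity Outbred, so by the cross males take their X chromosome from the mutant line. If that X chromosome was the same in all of them, X-linked genes should vary less between males than autosomal genes do, relative to females. With 0 components of variation removed they did not: the median log2 ratio of male to female SD was 0.73 for 469 X-linked genes and 0.65 for autosomes. With 5 components removed it was -0.02 and 0.06, and with 15 removed -0.10 and 0.02, below every autosome in both settings. These settings are consistent with a shared X chromosome in males, but with 0 removed the direction was the opposite, and the settings were tried after the first was seen.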
